A study of Mus musculus with 12 samples.

How the data were processed

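Total RNA of EMS404 cells was sequenced in 12 libraries, 3 for each combination of siRNA (scrambled or Bmal1) and treatment (vehicle or TGFb). Per the labels' protocols, RNA with an integrity number under 6.0 was discarded, RNA was prepared with 1 of 2 kits according to sample abundance, and libraries were built at BGI. Which sample went through which kit is not given in the sources used here. The series text calls the triplicates biological, but no label says that they came from separate cultures, so the p-values measure the spread between these samples, which may be in part technical. Groups were taken from the sample titles.

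Expression was deposited as FPKM (fragments per kilobase, relative to library size), per the file headers, in one table with 2 decimals. The submitters' processing notes name the genome build mm10, HISAT2 2.0.4, Bowtie2 2.2.5, RSEM and DESeq2, without the role of each. The annotation version, the use of strand, the siRNA sequence and the read numbers are not given in the sources used here. FPKM values are scaled to each library's size by the authors, so a change in a few abundant genes shifts all others. The counting error cannot be read from them. The design written beforehand assumed RPKM; FPKM takes the same test, and no whole reads could be recovered from it. The smallest steps between low values gave a rough depth of about 28100000 to 30000000 fragments per library, from 20 to 29 genes each and an assumed fragment length of 150 bases. At such a depth genes with an FPKM well below 1 rest on few fragments, and their fold changes are imprecise.

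The table held 16290 lines. Of these 555 had no gene identifier and held 1.304% to 1.464% of a library's FPKM total; they were left out of the tests. For 15 repeated identifiers the line with the lower mean was dropped, which left 15720 identifiers. Symbols and coordinates came from the GENCODE M21 annotation of mm10, which matched 15694 of them. Without stated strand use, reads of overlapping genes cannot be told apart: of 83 genes checked among those named, 31 shared exon bases with another annotated gene, in 15 cases a protein-coding one. The overlap is given beside only some of these genes. Members of near-identical families (Hist1h4i, Aldh1a1 and Aldh1a7, Apol9b, Oas1a) are uncertain too, since their sequences are alike whatever the strand.

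Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, in a group-means model over all 12 libraries with an intensity trend (8 residual and 5 prior degrees of freedom), two-sided, for 11208 genes with a mean of at least 0.5 FPKM. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates changes of low genes. All adjusted p-values for genes are from this fit unless another is named. The comparisons were TGFb against vehicle with each siRNA, Bmal1 against scrambled siRNA under each treatment, and the interaction of both. The strength of the response was the median signed interaction over genes called on the average TGFb effect, a contrast that is orthogonal to the interaction, with exact permutation of the siRNA labels within treatments.

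Gene lists, 42 with 1022 entries, were tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg adjustment over the 39 lists that had at least 5 tested genes. Each list's count of called genes is given over all genes tested and adjusted over the list alone. An estimated correlation and fry were alternatives. The genes named were Bmal1, the 10 called genes with the largest rise and the largest fall per pairwise comparison (groups not overlapping, a mean of at least 1 FPKM in the higher group, no predicted gene models), the 5 largest in each direction for the interaction, up to 4 called members per list or, where none was called, up to 2 with the smallest p, and any clock gene. Some genes that meet this rule are not reported here. Genes outside this rule are said to have been chosen after their values were seen. The tests, the lists, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to have been added later and the tests of the closing section.

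Alternatives were pseudocounts of 0.1 and 5, no filter and a mean of at least 2 FPKM, median-of-ratios scaling, scaling to equal totals, quantile normalization, the replicate number as a block, only the groups compared, limma without trend or with robust fitting, a 2-fold minimum, array weights and each library left out in turn. A fit that left out both second TGFb libraries was added after the data were seen. The fits were tested on simulated data with 200 genes changed by a log2 of 0.5, 1 or 2 among 11208. At a log2 change of 1 they recovered 98.5% of the changed genes for both comparisons of TGFb with vehicle and for the siRNA under vehicle, 100% for the siRNA under TGFb and 95.5% for the interaction. At a log2 change of 0.5 the interaction recovered 52.2%. Unchanged genes called numbered 9 (TGFb with scrambled siRNA), 17 (siRNA under vehicle), 15 (siRNA under TGFb), 6 (TGFb after Bmal1 siRNA) and 8 (interaction), so for the siRNA comparisons the share of false calls was above the nominal 5% in this simulation. Words of 7 bases in annotated 3' UTRs were ranked by a rank-sum z of the effect over its standard error in the genes carrying them, after regression on the length and GC content of the 3' UTR, with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.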

Results

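RNA sequencing was used to ask how an siRNA against a core clock factor alters the response of hepatic stellate cells to TGFb. EMS404 is an SV40-immortalised mouse hepatic stellate cell line on a C57Bl6 background that expresses human TLR4. Stellate cells are the vitamin A-storing cells of the liver sinusoid, and TGFb drives their conversion into matrix-producing myofibroblasts. Cells were transfected with a scrambled siRNA or with an siRNA against Bmal1, the clock transcription factor encoded by Arntl, and 48 h later received vehicle or 10 ng/mL TGFb for 24 h. The 4 groups held 3 libraries each, 12 in all. FPKM totals ran from 445472 (scrambled siRNA, TGFb, replicate 1) to 483957 (scrambled siRNA, vehicle, replicate 1), and 13673 to 13975 genes had a value above 0. Sequencing depth was not given. A rough estimate from the smallest steps of low values came to about 28100000 to 30000000 fragments per library. Pearson correlations across genes lay between 0.9912 and 0.9983 within groups. The first principal component held 71% of the variance. On it the 6 vehicle libraries lay between -17.76 and -15.42 and the scrambled TGFb libraries between 27.16 and 29.85. The Bmal1 siRNA TGFb libraries fell between these at 12.99, -5.13 and 8.4 for replicates 1 to 3.

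Bmal1 transcript (Arntl, ENSMUSG00000055116, mm10 chromosome 7, 113207465 to 113314126, plus strand) was lower with its siRNA under both treatments. It stood at 5.18 ± 0.26 FPKM (SD, n = 3) with scrambled siRNA and vehicle and at 3.79 ± 0.171 FPKM after Bmal1 siRNA, 26.9% less. TGFb brought it to 10.7 ± 0.184 FPKM with scrambled siRNA but 4.35 ± 0.603 FPKM after Bmal1 siRNA, 59.3% less. The difference under TGFb may hold a smaller rise with TGFb as well as the knockdown, which cannot be told apart here. In each comparison every library of one group lay above every library of the other, which with 3 against 3 gives a two-sided exact permutation p of 0.1, the smallest such a design allows. In the limma fit the log2 change with TGFb was 0.92 with scrambled siRNA (adjusted p = 6.4e-07), and the siRNA lowered the transcript by a log2 change of -1.13 under TGFb (adjusted p = 1.38e-06). The vehicle knockdown of -0.37 (SE 0.075) passed narrowly, with an adjusted p of 0.049. That call ended in every fit that left out a library of either vehicle group (adjusted p 0.0655 to 0.21) or of the scrambled TGFb group (0.0565 to 0.0802), and without Bmal1 siRNA TGFb replicate 3 (0.0662). It also ended with a pseudocount of 5 (0.0516), with no filter on low values (0.0812) and with libraries scaled to equal totals (0.0664).

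Other clock genes differed in level with TGFb, with the siRNA or with both. All libraries were taken at a single time, 24 h after treatment. A change in level can therefore not be told apart from a change in the timing of a rhythm. With scrambled siRNA, TGFb raised the repressors Bhlhe40, from 19.0 to 52.4 FPKM (log2 1.42), and Nfil3, from 16.5 to 32.7 FPKM (log2 0.95), together with Bhlhe41 (0.79), Arntl2 (0.39), Ciart (0.34), Clock (0.31) and Cry1 (0.19). It lowered the output regulators Dbp (-0.97, 539 exon bases shared with Sphk2) and Tef (-0.63), as well as Fmo2 (-0.89), Per3 (-0.35), Wee1 (-0.27), Per2 (-0.26) and Per1 (-0.17). Of the 16 tested E-box clock targets, 5 rose and 8 fell (6 and 8 adjusted over the list alone), and the list test gave no direction (camera adjusted p = 0.994). Under vehicle the Bmal1 siRNA lowered 2 of these 16 and raised none, by limma. Adjusted over the list alone, 7 were higher and 2 lower, and the list was not called (camera adjusted p = 0.143). The pair was Nr1d1, the REV-ERBα gene and a direct Bmal1 target, and Nr1d2. Nr1d1 (263 exon bases shared with Thra) went from 7.21 ± 0.146 to 4.31 ± 0.411 FPKM (log2 -0.63). Nr1d2 went from 6.21 ± 0.825 to 4.16 ± 0.397 FPKM (log2 -0.48). The Nr1d1 call ended without scrambled vehicle replicate 1 or 3 (adjusted p 0.0848 and 0.0764) or Bmal1 siRNA vehicle replicate 2 or 3 (0.161 and 0.117), and the Nr1d2 call ended in 9 of the 12 such fits (0.0591 to 0.195). Under TGFb the Bmal1 siRNA lowered Bhlhe40 (log2 -1.24), Bhlhe41 (-0.61), Nfil3 (-0.56) and Nr1d1 (-0.33) and raised Dbp (0.77) and Wee1 (0.21). After Bmal1 siRNA, TGFb raised Nr1d2 (0.52), Nr1d1 (0.49) and Nfil3 (0.33) and lowered Fmo2 (-1.03) and Per2 (-0.43). The interaction was not called for Nr1d1 (0.30, adjusted p = 0.164) or Nr1d2 (0.30, adjusted p = 0.162), so a difference from control cells was not shown for them. With TGFb after Bmal1 siRNA 2 of the 16 E-box targets rose and 5 fell (2 and 8 adjusted over the list alone), and the list was lower by the preset test (median -0.21, camera adjusted p = 0.0404; adjusted p = 0.505 with an estimated correlation). This call ended without scrambled vehicle replicate 1 (0.0506), Bmal1 siRNA vehicle replicate 3 (0.106), Bmal1 siRNA TGFb replicate 1 (0.0518) or 2 (0.07), and among genes with a mean of at least 2 FPKM (0.239).

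**Figure D1:**
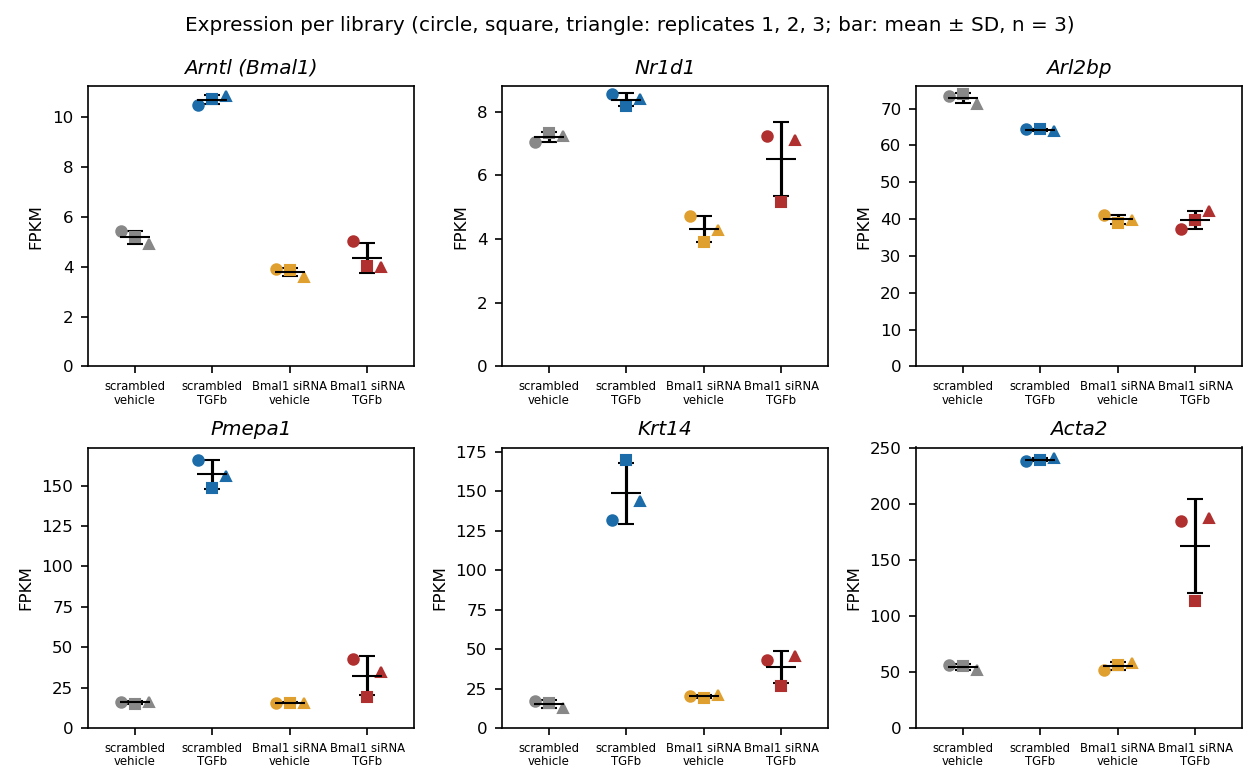
FPKM of Arntl, Nr1d1, Arl2bp, Pmepa1, Krt14 and Acta2 in each of the 12 libraries (points), by siRNA and treatment, with group mean ± SD (n = 3). The Arntl mean was 10.7 FPKM with scrambled siRNA and TGFb and 4.35 FPKM with Bmal1 siRNA and TGFb, and that of Pmepa1 was 157 and 32.3 FPKM.

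The response of control-transfected cells to TGFb was broad. Periostin (Postn), a matrix protein, went from 1.22 ± 0.223 to 36.4 ± 2.01 FPKM, and the laminin chain Lamb3 from 0.173 ± 0.015 to 11.2 ± 2.48 FPKM. Pmepa1 (chromosome 2, 173224458 to 173276533, minus strand), an inhibitor of TGFb signalling that the pathway itself induces, rose from 15.7 ± 0.667 to 157 ± 8.75 FPKM. The basal keratin Krt14 rose from 15.2 ± 2.31 to 149 ± 19.4 FPKM. The largest change belonged to the protease gene Ctsw (chromosome 19, 5465043 to 5468507, minus strand; 9 exon bases shared with Fibp), from 0.337 ± 0.22 to 60.5 ± 0.168 FPKM. Mfap4, the ectonucleotidase CD73 gene Nt5e, Fam20a and the desmosomal Pkp1 were among the other large rises, with log2 changes of 2.87 to 3.25. Among the 10 largest falls were the growth factor gene Ptn (59.0 ± 6.38 to 4.47 ± 0.465 FPKM), Rasl11a (96.2 ± 4.84 to 12.7 ± 0.442 FPKM), Id2, an inhibitor of helix-loop-helix factors (15.6 ± 0.428 to 1.52 ± 0.51 FPKM), and Lgals2 (126 ± 9.21 to 21.9 ± 4.15 FPKM). Haptoglobin (Hp), Vstm2a, the lipopolysaccharide-binding protein gene Lbp, Gdf10 and Clca3a1 were also among them. The limma fit called 5105 of 11208 genes, 1841 higher and 3264 lower, of which 214 and 219 changed at least 2-fold. The share of higher calls, 36.1% on the deposited scale, was 49.8% with median-of-ratios scaling and 47.5% after quantile normalization, so the balance of rises and falls depended on the scaling.

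In control cells more matrix, contractile and TGFb pathway genes were called higher than lower with TGFb. Of 27 TGFb pathway genes 18 rose and 7 fell (18 and 7 adjusted over the list alone), led by Pmepa1 (log2 3.24), Id2 (-2.74), Ldlrad4 (2.37) and Ltbp2 (2.14). Of 13 fibrillar and associated collagens 9 rose and 2 fell (9 and 2 adjusted over the list alone), among them Col6a3 (1.92) and Col5a1 (1.60). Col1a1, singled out after its values were seen, went from 2784 to 4130 FPKM (log2 0.57, adjusted p = 8.08e-06). The matrix glycoproteins had 11 of 20 higher and 4 lower (11 and 4 adjusted over the list alone), with Postn (4.08) and fibrillin (Fbn1, 2.46) up and decorin (Dcn, -2.37) down. Collagen processing enzymes had 12 of 22 higher and 2 lower (12 and 2 adjusted over the list alone), including Pcolce2 (1.73), Lox and the lysyl hydroxylase Plod2 (0.90). Contractile genes had 16 of 25 higher and 4 lower (18 and 4 adjusted over the list alone), led by smooth muscle actin (Acta2, 54.4 to 240 FPKM, log2 2.12) and Tagln (1.47). Of 14 EMT factors 11 rose and 2 fell (11 and 3 adjusted over the list alone), with Runx1 (2.45) and Snai1 (1.74) among them. ATF4 targets of the integrated stress response had 20 of 24 higher and 1 lower (23 and 1 adjusted over the list alone; Fgf21 1.67, Trib3 1.38). Cholesterol synthesis had 1 of 25 higher and 21 lower (1 and 23 adjusted over the list alone; Dhcr7 -0.74), and nuclear oxidative phosphorylation genes 1 of 43 higher and 30 lower (1 and 31 adjusted over the list alone; Sdhc -0.54). Interferon response genes had 30 of 40 higher and none lower (31 adjusted over the list alone), with Oasl2 (2.27), Isg15 (2.13) and Usp18 (2.12) at the top. The libraries differed, and Isg15 stood at 15.8, 99.1 and 32.3 FPKM in replicates 1 to 3 against 6.75 to 8.28 FPKM under vehicle. Without replicate 2, 25 of 39 interferon genes were higher and the list's median log2 change went from 0.89 to 0.50. All of these lists were called by camera with its preset correlation, and none with an estimated correlation. The adjusted p was 0.113 for the TGFb pathway, matrix glycoproteins, collagen processing and ATF4, 0.131 for collagens, 0.14 for contractile and cholesterol genes, 0.255 for EMT factors, 0.458 for interferon and 0.491 for oxidative phosphorylation, with an estimated correlation in each case. Over all 39 lists, 20 were called with the preset correlation, 0 with the estimated one by camera and 30 by fry, which asks only whether a list moves one way on balance.

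Markers of other liver cells moved in both directions. Of 5 tested hepatocyte markers, Ass1 rose (log2 2.31) and 3 fell with TGFb in control cells, among them transferrin (Trf, -1.96) and Ahsg (-1.74); the count adjusted over the list alone was 1 higher and 3 lower and the list was not called (camera adjusted p = 0.59). Of 5 cholangiocyte and epithelial markers 3 rose, osteopontin (Spp1, 1.53), Krt8 (1.15) and Sox9 (0.80), and 2 fell, among them Krt7 (-0.71). Adjusted over the list alone the count was 3 and 2, and the list, with a median of 0.80, was not called by camera (adjusted p = 0.153) but was by fry (adjusted p = 0.000522). Mesothelial and portal fibroblast markers had 6 of 13 higher and 7 lower (6 and 7 adjusted over the list alone), with Mfap4 at 3.25 and Upk3b at -2.13. Their median was -0.56 and their mean 0.018, and the list was not called (camera adjusted p = 0.575). Quiescent stellate cell markers had 3 of 14 higher and 8 lower (3 and 8 adjusted over the list alone), with the PDGF receptor genes apart (Pdgfra -1.91, Pdgfrb 1.14), and were not called either (camera adjusted p = 0.503). With 4 tested genes each, leukocyte and endothelial markers were too few for a list test. Of the leukocyte genes Fcer1g rose (0.88) and Cd14 (-0.61) and Cd68 (-0.45) fell (1 and 2 also when adjusted over the list alone), and of the endothelial genes Eng rose (0.45) and Egfl7 fell (-0.49), 1 and 1 likewise adjusted over the list alone. The abundant leukocyte transcripts Lyz2, Laptm5 and Itgam reached at most 0.15 FPKM in any library.

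Without TGFb, fewer genes were called with the Bmal1 siRNA than in the other comparisons. Arl2bp (chromosome 8, 94666600 to 94674425, plus strand), which encodes a binding partner of the small GTPase ARL2, fell from 72.8 ± 1.45 to 39.9 ± 1.12 FPKM (log2 -0.85, adjusted p = 1.4e-06). Pea15a (chromosome 1, 172196728 to 172206804, minus strand; 123 exon bases shared with Dcaf8), which encodes a death-effector-domain protein, fell from 75.8 ± 1.95 to 53.9 ± 1.31 FPKM (log2 -0.48, adjusted p = 8.29e-05). Beside Nr1d1 and Nr1d2, the largest falls included Cd14, the lipopolysaccharide co-receptor (log2 -0.63), and Hand2, a transcription factor of stellate cells (-0.43), and the largest rises Cox6a2 (0.76) and the aryl hydrocarbon receptor Ahr (0.61). Among 18 hypoxia response genes 1 rose over all genes tested (Vegfa, 0.34) and 11 adjusted over the list alone, none fell, and the median log2 change was 0.44 (camera adjusted p = 6.76e-06; adjusted p = 0.774 with an estimated correlation). Of 27 glycolysis genes 1 rose (Hk2, 0.36; 2 adjusted over the list alone; camera adjusted p = 0.00462; adjusted p = 0.774 with an estimated correlation). Of 16 integrins and matrix receptors 1 rose (Itgb8, 0.48; 5 adjusted over the list alone; camera adjusted p = 0.0204, fry adjusted p = 0.00492; adjusted p = 0.659 with an estimated correlation). None of 13 collagens passed limma's threshold over all genes, with 3 higher adjusted over the list alone and Col5a2 at 0.27 and Col1a2 at 0.27 (camera adjusted p = 0.00466; adjusted p = 0.659 with an estimated correlation). Limma called 74 genes, 33 higher and 41 lower, none at 2-fold or more, with 2433 at an unadjusted p under 0.05; 44.6% of the calls were higher, against 61.8% with libraries scaled to equal totals. Of 12 lists called with the preset correlation, 0 held with the estimated one by camera. Fry called 1 of all 39 lists, the integrins. The count was 2 without scrambled vehicle replicate 1 or without Bmal1 siRNA vehicle replicate 3, 3 without scrambled vehicle replicate 3 or Bmal1 siRNA vehicle replicate 2, 12 and 46 without scrambled TGFb replicates 3 and 2, and 472 and 24 without Bmal1 siRNA TGFb replicates 2 and 3. It was 229 with only the groups compared, 414 without both second TGFb libraries and 1490 with array weights, so the small number of calls depended on the fit. Of the 28 genes named by rule in this comparison only Arl2bp and Pea15a kept their call in every setting other than a 2-fold minimum. The calls of Cd14 and Itgb8 ended in 4 of the 12 fits without a library (adjusted p 0.0683 to 0.161), Hand2 in 5 (0.0525 to 0.194), Ahr (0.0548 to 0.195) and Cox6a2 (0.0525 to 0.195) in 6, Hk2 in 8 (0.0543 to 0.252) and Vegfa in 9 (0.0502 to 0.252). The integrin list was not called among genes with a mean of at least 2 FPKM (camera adjusted p = 0.202).

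Under TGFb, the Bmal1 siRNA changed many genes. Pmepa1 fell from 157 ± 8.75 to 32.3 ± 11.97 FPKM (log2 -2.32, adjusted p = 5.74e-06), Krt14 from 149 ± 19.4 to 38.6 ± 10.3 FPKM (-1.95, adjusted p = 6.62e-06) and Pkp1 from 7.01 to 1.17 FPKM (-1.92). Ptn rose from 4.47 ± 0.465 to 22.7 ± 15.6 FPKM (log2 1.91, adjusted p = 0.000846), the neutrophil chemokine gene Cxcl1 from 2.22 ± 0.108 to 9.35 ± 2.27 FPKM (1.66). The BMP ligand genes were higher as well, Bmp4 from 13.6 to 36.6 FPKM (1.35) and Bmp2 from 4.99 to 13.1 FPKM (1.23). Rasl11a, ceruloplasmin (Cp), Mgp, Dcn, Lbp and Npy4r were the other largest rises. The interferon genes Oasl2, Usp18, Rtp4, Isg15 and Apol9b stood beside Mfap4 and Trabd2b among the other falls. Of 27 TGFb pathway genes 2 rose and 17 fell (4 and 19 adjusted over the list alone), with Junb (-1.55) and Ltbp2 (-1.32) beside Pmepa1. The matrix glycoproteins had 2 of 20 higher and 11 lower (2 and 12 adjusted over the list alone; Fbn1 -1.40, Postn -1.08). PDGF, IGF and FGF ligands and binding proteins had 4 of 21 higher and 11 lower (5 and 12 adjusted over the list alone, with Pdgfb -1.58 and Fgf21 -1.19). The list of endoplasmic reticulum chaperones and unfolded protein response genes had none of 23 higher and 7 lower (8 lower adjusted over the list alone, with Ern1 -0.41 and Xbp1 -0.34). These were the 4 of 21 called lists that held with an estimated correlation, with an adjusted p of 0.0141, 0.0322, 0.0182 and 0.0186; fry called 25 of all 39 lists. Contractile genes (1 of 25 higher and 11 lower, 1 and 11 adjusted over the list alone; Pdlim7 -0.64) and collagens (1 of 13 higher and 6 lower, 2 and 7 adjusted over the list alone; Col5a2 -0.53) were lower by the preset test, with an adjusted p = 0.108 for both with an estimated correlation. Interferon genes had none of 40 higher and 22 lower (30 lower adjusted over the list alone; median -0.84), with an adjusted p = 0.298 with an estimated correlation, and 18 of 39 lower with a median of -0.46 when scrambled TGFb replicate 2 was left out. Markers of other cells did not move together. Hepatocyte markers had 2 of 5 higher and 1 lower (2 and 1 adjusted over the list alone; Ahsg 0.94, Ass1 -1.39; median 0.42) and were not called (camera adjusted p = 0.889), and of 4 endothelial markers, too few for a list test, 1 rose (Egfl7, 0.28) and 1 fell (Eng, -0.29), against 2 and 1 adjusted over the list alone. The Egfl7 call ended in 4 of the 12 fits without a library (adjusted p 0.0744 to 0.126). By the preset test 2 other lists were lower. Of 5 cholangiocyte and epithelial markers none rose and 3 fell (1 and 3 adjusted over the list alone; Krt8 -0.86, Sox9 -0.55), with an adjusted p = 0.0969 with an estimated correlation. That call ended with no filter (camera adjusted p = 0.133) and with median-of-ratios scaling (0.0509). Of 13 mesothelial and portal fibroblast markers 2 rose and 5 fell (3 and 6 adjusted over the list alone; median -0.21), with an adjusted p = 0.298 with an estimated correlation. The direction depended on the summary, since the list's median per library was -0.643, -0.308 and -0.548 with scrambled siRNA and higher, at -0.442, 0.25 and -0.017, with Bmal1 siRNA, and this call ended without Bmal1 siRNA TGFb replicate 1 (camera adjusted p = 0.101), with median-of-ratios scaling (0.0509) and at a mean of at least 2 FPKM (0.0819). Limma called 2596 genes, 1794 higher and 802 lower, while of those changing at least 2-fold 30 were higher and 89 lower. The 69.1% share of higher calls became 44.9% with median-of-ratios scaling and 53.3% after quantile normalization.

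After the Bmal1 siRNA, TGFb still moved many of the same leading genes, often by smaller amounts. Ctsw rose from 0.26 ± 0.201 to 22.2 ± 12.7 FPKM, Postn from 1.43 ± 0.131 to 17.4 ± 6.10 FPKM, Igfbp7 from 19.3 ± 0.955 to 71.5 ± 24.4 FPKM and Acta2 from 55.4 ± 3.27 to 162 ± 42.1 FPKM (2.93-fold, adjusted p = 4.04e-05). The cardiac troponin gene Tnnt2, Lamb3, Fam20a, Nt5e and Cdsn were among the other large rises. The changes of Cdsn (log2 1.48, against 1.16 with scrambled siRNA) and Aldh1a7 (-1.78, against -1.65) were not smaller, and neither interaction was called (adjusted p = 0.259 and 0.795). Falls were led by the retinaldehyde dehydrogenase Aldh1a1 (39.0 ± 3.57 to 10.2 ± 6.40 FPKM), the mesothelial and urothelial marker Upk3b (187 ± 7.33 to 50.5 ± 22.8 FPKM) and Lgals2 (137 ± 12.7 to 36.3 ± 13.0 FPKM), with Lbp, Aldh1a7, Id2, Trf, Prg4 and Plagl1 among the others. Aldh1a1 and Aldh1a7 are close copies whose values are not independent. Cholesterol synthesis had none of 25 higher and 20 lower (23 lower adjusted over the list alone; Stard4 -0.57, Insig1 -0.50; adjusted p = 0.157 with an estimated correlation). ATF4 targets had 18 of 24 higher and none lower (18 and 1 adjusted over the list alone; Cth 0.95, Trib3 0.71; adjusted p = 0.303 with an estimated correlation). Serine, proline and glutamine metabolism had 12 of 21 higher and 1 lower (15 and 1 adjusted over the list alone; Shmt2 0.63; adjusted p = 0.472 with an estimated correlation). Glycolysis had none of 27 higher and 8 lower (17 lower adjusted over the list alone; Aldoc -0.76; adjusted p = 0.505 with an estimated correlation), and hypoxia response none of 18 higher and 6 lower (9 lower adjusted over the list alone; Car9 -1.52; adjusted p = 0.626 with an estimated correlation). The TGFb pathway list was not called (camera adjusted p = 0.819). In it 10 of 27 were higher and 6 lower (10 and 7 adjusted over the list alone), with Id2 (-1.70), Id3 (-1.47), Id1 (-1.40) and Ltbp1 (1.09) in front. Its median was 0.009, which turned to -0.006 with libraries scaled to equal totals, and its mean -0.048. Limma called none of 40 interferon genes, also adjusted over the list alone (Ifih1 -0.58), but the list, with a median of -0.24, was lower by the preset test (camera adjusted p = 0.0402; adjusted p = 0.836 with an estimated correlation). This call ended without scrambled vehicle replicate 1 (0.0569), Bmal1 siRNA vehicle replicate 2 (0.301) or Bmal1 siRNA TGFb replicate 1 (0.144) or 2 (0.081), with a pseudocount of 5 (0.0803) and with no filter (0.05). Limma called 2128 genes, 998 higher and 1130 lower, and of the 16 lists called with the preset correlation 0 held with the estimated one by camera. Fry called 14 of all 39 lists. The count became 3265 without Bmal1 siRNA TGFb replicate 2, 1316 and 1171 without replicates 1 and 3 of that group, and 1294 and 1336 without Bmal1 siRNA vehicle replicates 2 and 3.

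**Figure D2:**
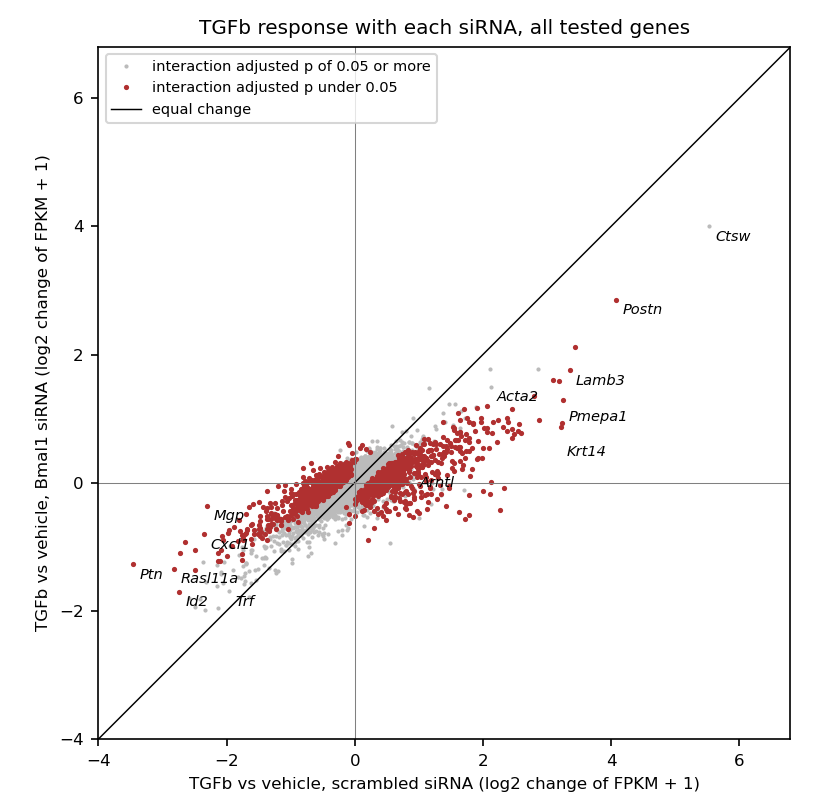
Log2 change of FPKM + 1 with TGFb for each of 11208 genes with scrambled siRNA (x axis) and after Bmal1 siRNA (y axis), in red where the interaction had an adjusted p under 0.05, with the line of equal change. Most red genes changed less after Bmal1 siRNA than with scrambled siRNA, for example Pmepa1 at an interaction of -2.31.

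The interaction tested the difference between the TGFb responses directly. The rise of Pmepa1 was smaller after the Bmal1 siRNA by a log2 difference of -2.31 (SE 0.27, adjusted p = 0.000181) and that of Krt14 by -2.34 (SE 0.233, adjusted p = 7.07e-05). The falls of Ptn (2.18), Mgp (1.95), Vstm2a (1.73), Hp (1.62) and Cxcl1 (1.55) were smaller too, and with Oasl2 (-2.70), Apol9b (-2.42) and Usp18 (-2.29) these were the largest differences. Usp18 differed widely between the scrambled TGFb libraries (1.75, 17.29 and 5.06 FPKM), and its call ended in 7 of the 12 fits that left out a library, with an adjusted p of 0.0524 to 0.0764. Among clock genes the difference was negative for Bhlhe40 (-1.78), Bhlhe41 (-0.93), Arntl itself (-0.77, adjusted p = 0.000526), Ciart (-0.73) and Nfil3 (-0.62). Acta2, singled out after its values were seen, differed by -0.62 without passing (adjusted p = 0.0526). Of 27 TGFb pathway genes 1 was higher and 16 lower (1 and 17 adjusted over the list alone; Ldlrad4 -1.57), and of 20 matrix glycoproteins none and 10 (1 and 12 adjusted over the list alone; Fbn1 -1.76). Of 22 collagen processing genes 1 was higher and 6 lower (1 and 8 adjusted over the list alone; Lox -1.16), and of 16 integrins and matrix receptors 2 and 9 (2 and 9 adjusted over the list alone; Itgb3 -1.24). PDGF, IGF and FGF ligands and binding proteins had 4 of 21 higher and 9 lower (6 and 10 adjusted over the list alone, with Pdgfb -1.81). Endoplasmic reticulum chaperones and unfolded protein response genes had none of 23 higher and 6 lower (0 and 6 adjusted over the list alone, with Xbp1 -0.46). Clock activators had none of 5 higher and 2 lower (0 and 3 adjusted over the list alone). Those 7 of the 24 called lists held with an estimated correlation, with adjusted p-values of 0.0142, 0.0187, 0.0342, 0.0187, 0.0187, 0.0187 and 0.0424; fry called 20 of all 39 lists. Collagens had none of 13 higher and 8 lower (9 lower adjusted over the list alone; Col6a3 -1.26), with an adjusted p = 0.0559 with an estimated correlation. Interferon genes had none of 40 higher and 18 lower (34 lower adjusted over the list alone; median -1.12), with an adjusted p = 0.297 with an estimated correlation. Cholangiocyte and epithelial markers had none of 5 higher and 2 lower (3 lower adjusted over the list alone; Krt8 -1.45), with an adjusted p = 0.0784 with an estimated correlation, and the call by the preset test ended with no filter (camera adjusted p = 0.0639). Mesothelial and portal fibroblast markers had 1 of 13 higher and 5 lower (1 and 6 adjusted over the list alone; median -0.25), with an adjusted p = 0.297 with an estimated correlation, and that call ended without Bmal1 siRNA TGFb replicate 1 (0.0582). By medians per library the mesothelial and portal fibroblast list went the other way, falling less with TGFb after the Bmal1 siRNA. These medians were -0.643, -0.308 and -0.548 with scrambled siRNA and TGFb and -0.442, 0.25 and -0.017 with Bmal1 siRNA and TGFb. Under vehicle they ran from -0.103 to 0.092. Without scrambled TGFb replicate 2 the interferon list had 21 of 39 lower and a median of -0.77. Limma called 1612 genes, 993 higher and 619 lower (28 and 118 at 2-fold or more), and 991 without Bmal1 siRNA vehicle replicate 2. The share of higher calls was 61.6%, and 42.1%, 44.9% and 49.4% with median-of-ratios scaling, scaling to equal totals and quantile normalization.

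Over the whole response, TGFb effects were smaller after the Bmal1 siRNA. Among 5218 genes called on the TGFb effect averaged over both siRNAs, 4210 (80.7%) had a smaller response after knockdown, 1243 of them by a called interaction, and 18 genes had a called larger one. The median interaction in the direction of each gene's response was -0.17 on the log2 scale, with a two-sided exact permutation p of 0.015 over 400 assignments of the siRNA labels, where 0.005 was the smallest possible. Measured as a slope on the mean response of control cells, the Bmal1 siRNA TGFb libraries reached 62.8%, 26.7% and 53.5% in replicates 1 to 3, against 98.4% to 102.8% for the scrambled TGFb libraries that define the scale. Without Bmal1 siRNA TGFb replicate 2 the median was -0.11 (exact permutation p = 0.05 over 200 assignments), and without Bmal1 siRNA vehicle replicate 1 it was -0.16 (exact permutation p = 0.08). The exact permutation p was also not under 0.05 with libraries scaled to equal totals, with array weights or without both second TGFb libraries. Those values are given further below. The TGFb effects with either siRNA correlated at 0.753 across genes, which are not independent replicates. They share no library: 689 genes were called higher in both (163.9 for independent lists), 967 lower in both (329.1) and 34 in opposite directions.

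**Figure D3:**
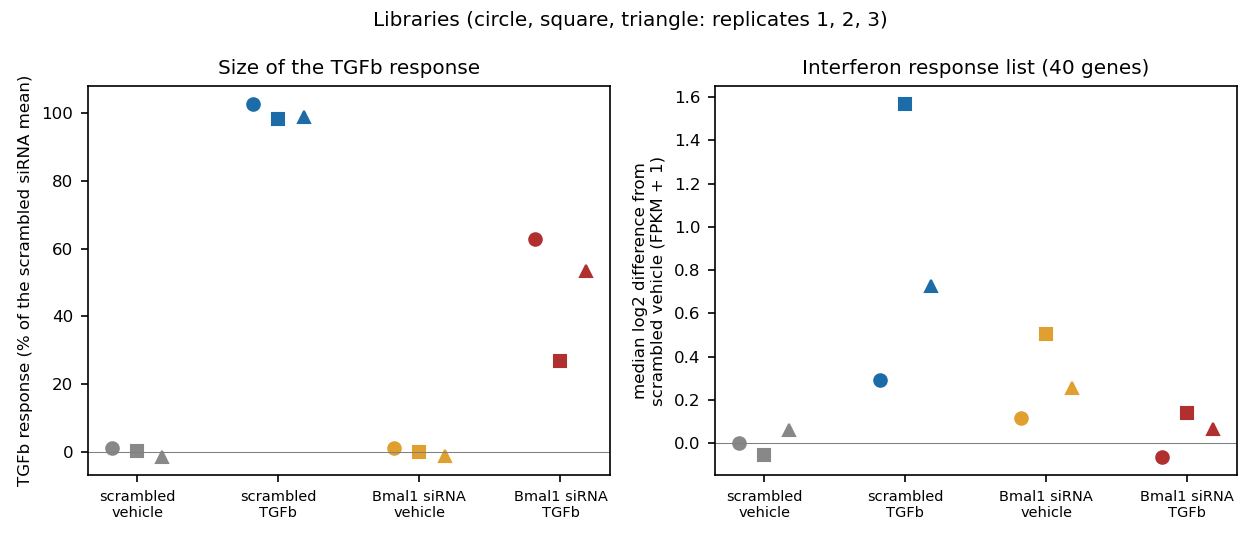
For each library, the TGFb response as a percent of the mean response of scrambled siRNA libraries (left) and the median log2 difference of interferon response genes from the scrambled vehicle mean (right). Bmal1 siRNA TGFb replicate 2 reached 26.7% on the left, and scrambled TGFb replicate 2 stood at 1.57 on the right.

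The siRNA effects under vehicle and under TGFb were not correlated across genes. Their correlation over the 11208 genes was -0.020 (covariance -0.00072), and these contrasts share no library. It was -0.103 and 0.022 without Bmal1 siRNA TGFb replicates 2 and 1, and -0.075 and 0.018 without scrambled TGFb replicates 1 and 2. Under vehicle 74 genes were called, none at 2-fold or more. With effects this small, the spread between libraries can weaken the correlation, so it cannot show that the siRNA effects differ. Of 28 genes called in both, 12 moved the same way. Lower in both were 10 genes, against 2.93 for independent lists, among them Arl2bp, Pea15a, Nr1d1, Arntl, Ampd2, Med10, Irx1, Icmt and Cacnb3, and 2 were higher in both, Itgb8 and Sema3a, against 5.28. Arl2bp (-0.85 and -0.68) and Pea15a (-0.48 and -0.38) fell by similar amounts. The other 16 moved in opposite directions, among them Vegfa (0.34 and -0.77), Hk2 (0.36 and -0.43), Lox (0.48 and -0.68), Ahr (0.61 and -0.58) and Hand2 (-0.43 and 0.42). All genes of this count were taken because they passed in both comparisons, and the vehicle calls other than Arl2bp and Pea15a depended on the libraries as described for the vehicle comparison.

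**Figure D4:**
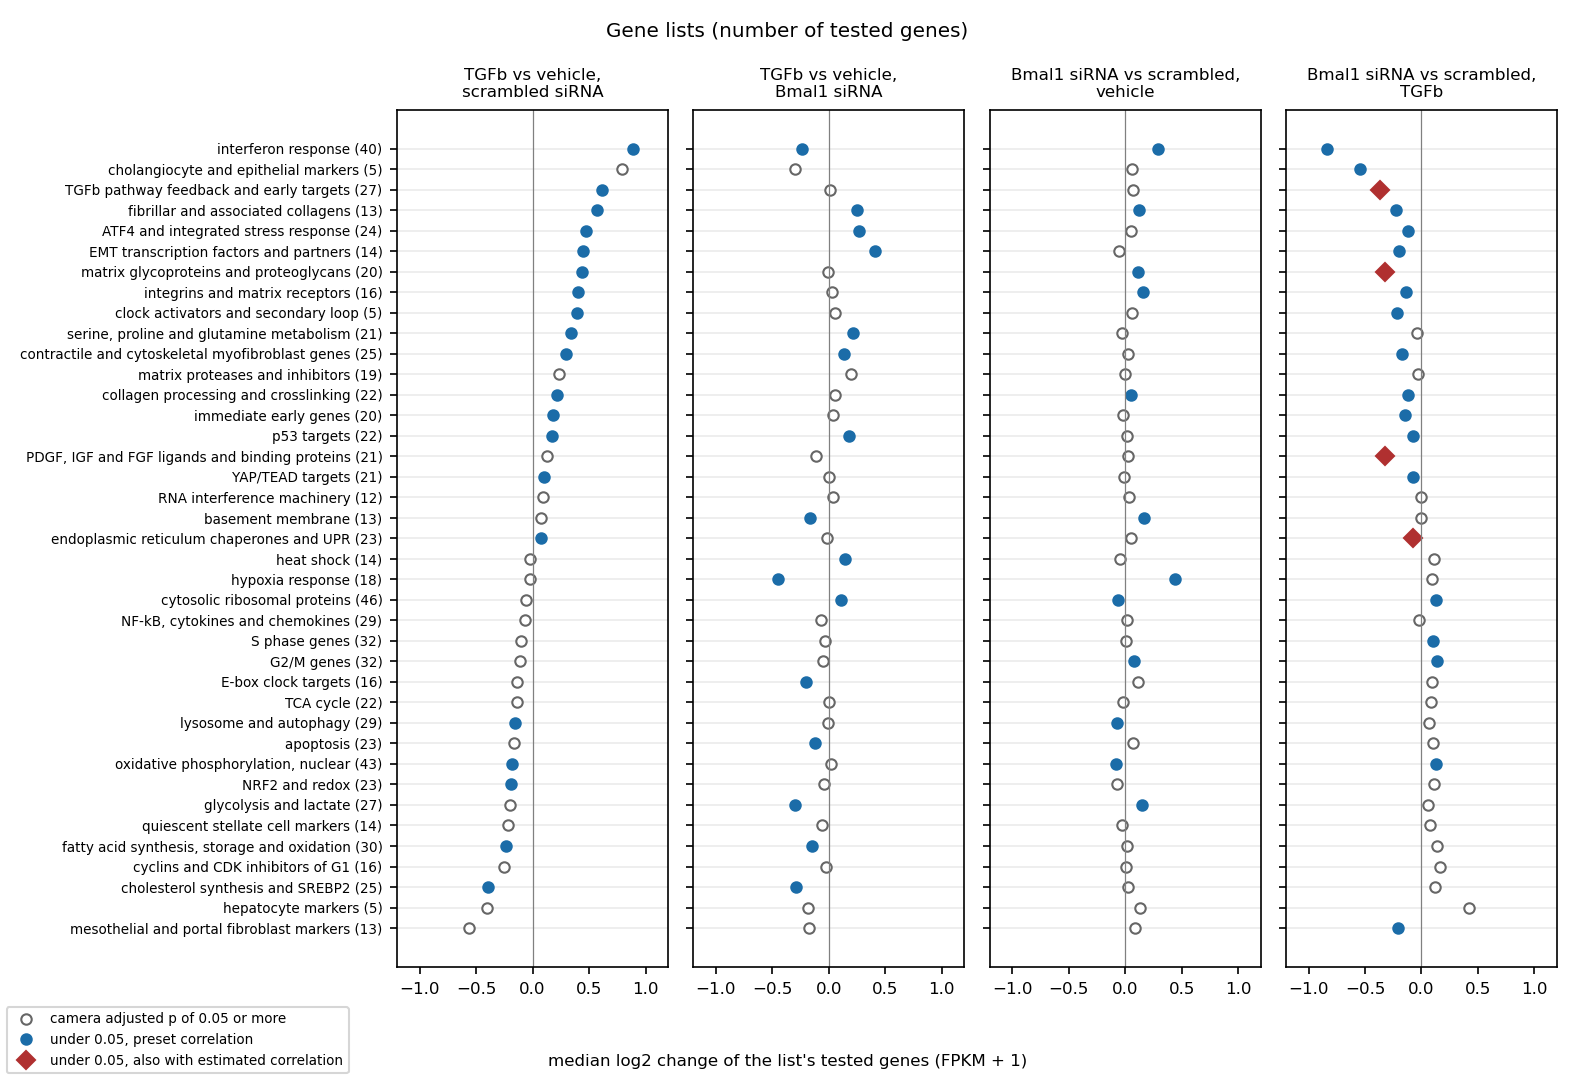
Median log2 change of the tested genes of each of 39 lists in the 4 pairwise comparisons: open symbols were not called, blue ones were called with camera's preset correlation and red diamonds also with an estimated correlation. Red diamonds appear for 4 lists, all with Bmal1 siRNA under TGFb; medians near 0 change sign with the scaling, such as 0.009 for the TGFb pathway with TGFb after Bmal1 siRNA.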

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

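Chosen after the result was seen were the test of a single weak library, the test on leukocyte transcripts, and the use of the planned permutation of siRNA labels and of the interferon list's values as tests of explanations. The mixture test and the rescalings were set once the patterns had been noticed but before their own values were seen, and the splits of the libraries before their counts were seen.

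Bmal1 siRNA TGFb replicate 2 lay nearer to the vehicle libraries than replicates 1 and 3, with 26.7% of the control response against 62.8% and 53.5%. Mixing in of RNA or cells from a vehicle culture would leave risen and fallen genes with the same share of the change of the other replicates. The median share was 0.398 for risen genes (95% bootstrap interval over genes 0.366 to 0.453, 170 genes). It was 0.535 for fallen genes (0.503 to 0.549, 397 genes), a difference of 0.137. Slopes on the control response also differed between risen and fallen genes in replicate 1 (52.5% and 71.6%) and replicate 3 (46.6% and 59.5%). The intervals cover genes and not the spread between libraries, so the difference cannot decide for or against such a mixture. A weaker or shorter exposure to TGFb in that well, a different transfection or the RNA kit may also account for the position of replicate 2. These data hold no test of them.

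The TGFb response was smaller after the Bmal1 siRNA, with 1612 genes and 24 gene lists called for the interaction. Leaving out replicate 2 of that group kept a median signed interaction of -0.106, 63.4% of the value with all libraries but with an exact permutation p of 0.05, and the smallest value over 3 rescalings was -0.145, so neither that library nor the authors' scaling accounts for all of it. Of 400 assignments of the siRNA labels, a share of 0.015 gave a median as large, and 2 of 100 drawn assignments, the real one included, gave as many called genes; the other, with 1828 genes, exchanged all vehicle siRNA labels, which turns the difference of the siRNA effects into their sum. These shares argue against chance labels, but not firmly, since the share for the median was 0.05 scaled to equal totals, 0.145 with array weights and 0.183 without both second TGFb libraries. An effect of Bmal1 on TGFb signalling, an effect of this siRNA on other transcripts and unequal TGFb exposure between the transfections stay open, and no second siRNA was analysed here.

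Interferon response genes were higher in the scrambled TGFb libraries, with a median log2 difference from scrambled vehicle of 0.293, 1.57 and 0.727 in replicates 1 to 3. The lowest of these lay above all 3 scrambled vehicle libraries (-0.056 to 0.059), whose mean is the reference. Bmal1 siRNA vehicle replicate 2 stood at 0.503 without TGFb, so scrambled TGFb replicate 1 was not outside the range of all vehicle libraries. Scrambled TGFb replicate 3, at 0.727, lay above every vehicle library, which argues against replicate 2 as the whole source. After Bmal1 siRNA the median change with TGFb was -0.238, which argues against TGFb irrespective of the siRNA. The median of the leukocyte list decided nothing, and a test on abundant leukocyte transcripts was then chosen: Lyz2, Laptm5 and Itgam reached at most 0.15 FPKM in these libraries, too low for leukocyte RNA as the source. Replicate 2 had the highest interferon median of its group, followed by 3 and then 1, in 3 of the 4 groups (0.117, 0.503 and 0.253 for Bmal1 siRNA vehicle). A response to transfected RNA or a condition shared by libraries of one number may contribute and was not tested.

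The other results drawn out by the test of the interaction were single genes, with log2 differences of 2.18 for Ptn, 1.95 for Mgp, 1.73 for Vstm2a, 1.62 for Hp, 1.55 for Cxcl1, -2.70 for Oasl2, -2.42 for Apol9b, -2.34 for Krt14, -2.31 for Pmepa1 and -2.29 for Usp18. Clock genes among them were Bhlhe40 (-1.78), Bhlhe41 (-0.93), Arntl (-0.77), Ciart (-0.73), Nfil3 (-0.62) and Dbp (0.78). The Dbp call ended without scrambled vehicle replicates 1 or 3 (adjusted p 0.0609 and 0.0667), scrambled TGFb replicate 1 (0.062) or Bmal1 siRNA vehicle replicates 1 or 3 (0.0692 and 0.0537). Among table lines without a gene identifier, outside the main tests, 39 of 149 were called with TGFb and scrambled siRNA, 15 of them higher.

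Splits of the 6 libraries of each pairwise comparison number 10, too few for a share under 0.05: 1 of the 10, the real split, reached the real count. The real splits called 5105 genes (TGFb with scrambled siRNA), 74 (siRNA under vehicle), 2596 (siRNA under TGFb) and 2128 (TGFb after Bmal1 siRNA), and the highest other split called 0 by limma in each.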

How the results depend on the processing

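The fit without both second TGFb libraries was the only alternative chosen after the result was seen. No call of a named gene or of a list turned into a call of the other direction under any alternative. The other called genes were counted but not followed one by one. A 2-fold minimum left 433, 0, 119, 99 and 146 genes for TGFb with scrambled siRNA, the siRNA under vehicle (where limma had 2433 at an unadjusted p under 0.05), the siRNA under TGFb, TGFb after Bmal1 siRNA and the interaction, by its construction. Array weights gave 1490, 4914, 5513 and 3723 in the last 4, with a warning of incomplete convergence. Only the groups compared gave 229 under vehicle and 1542 under TGFb for the siRNA, and leaving out both second TGFb libraries 414, 1489 and, for TGFb after Bmal1 siRNA, 3246. The siRNA under vehicle called 7 genes with no filter. Leaving out 1 library in turn gave 4385 to 5468, 2 to 472, 1850 to 2921, 1171 to 3265 and 991 to 1872. Bmal1 under vehicle kept its sign but not its call at -0.21 (pseudocount 5), -0.37 (no filter; 2-fold minimum) and -0.38 (equal totals), and moved from -0.40 to -0.34 leaving out 1 library; under TGFb it kept its call from -1.23 to -1.09. The strength of the response was -0.166 scaled to equal totals (exact permutation p = 0.05), -0.094 with array weights (0.145), -0.12 without both second TGFb libraries (0.183) and -0.209 to -0.106 leaving out 1 library. The correlation of the siRNA effects was -0.113 with array weights, -0.062 without both second TGFb libraries and -0.103 to 0.022 leaving out 1 library. With an estimated correlation 0, 0, 4, 0 and 7 lists were called by camera, fry called 1 under vehicle, and leaving out 1 library gave 18 to 21, 10 to 13, 19 to 22, 12 to 16 and 22 to 25. Except for the 2-fold minimum the cause was not tested. Counted per gene, comparison and alternative, the outcome for named genes was unchanged in 14985 cases, weaker in 1435 and stronger in 8, and for lists unchanged in 4787, weaker in 205 and stronger in 63. Named genes were counted largely because they were called, so most could lose a call but not gain one. The 2-fold minimum, which removes calls by construction, gave 420 of their changed cases.

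No label says that replicate numbers pair the samples, and the values leave it open: libraries with the same number correlated at -0.149 to 0.475 in their deviations from the group means, 6 of 12 correlated best with their own number, and replicate 1 had the lowest hypoxia and glycolysis list medians in all 4 groups. With the replicate block 540 genes were called for the siRNA under vehicle, including all 74, and 5360 for TGFb with scrambled siRNA, so the number of calls under vehicle depends on whether a shared number means a shared condition. Count-based tests were not run, because no counts or whole reads could be recovered. Depth limits what can be said of genes under about 1 FPKM, and the interaction, which recovered 52.2% of simulated log2 changes of 0.5, misses many small differences.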

Other observations

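The search for 7-base words was set after the genes lower under both treatments had been seen but before any word was ranked, while the look at Arntl transcripts, the Fisher test and the repeats without called genes were chosen after its result was seen. In control cells TGFb also moved members of other groups, of which 5 are described here: fatty acid and NRF2 genes were lower by the preset test, and S phase genes, G1 regulators and inflammatory genes were not called as lists. Of 30 genes of fatty acid synthesis, storage and oxidation 2 rose and 19 fell (2 and 21 adjusted over the list alone), led by the hormone-sensitive lipase Lipe (log2 -1.30), with monoglyceride lipase (Mgll, 0.97) against the trend; the adjusted p = 0.168 with an estimated correlation, against 0.00504 with the preset one. NRF2 and redox genes had 1 of 23 higher and 15 lower (2 and 16 adjusted over the list alone), with the glutathione transferase Gstm1 at -2.06 and the cystine transporter Slc7a11 at 0.97; the adjusted p = 0.234 with an estimated correlation, against 0.0128 with the preset one. S phase genes had 1 of 32 higher and 14 lower (1 and 14 adjusted over the list alone; camera adjusted p = 0.0516, not called), and of the regulators of G1 cyclin D1 (Ccnd1, -1.99) fell while the cell-cycle inhibitors Cdkn1a (1.79) and Cdkn2b (1.49) rose, in a list with 4 of 16 higher and 9 lower (4 and 9 adjusted over the list alone; camera adjusted p = 0.64). Inflammatory genes split: of 29, 9 rose and 13 fell (10 and 14 adjusted over the list alone; camera adjusted p = 0.92), with Cxcl1 (-2.35), Saa3 (-2.09) and complement C3 (-1.78) down and Ptgs2 (1.64) up; the median was -0.063 and the mean -0.19, while camera's direction was up.

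A hypothesis was that part of the genes lower after the Bmal1 siRNA carry a seed match of that siRNA, a short stretch in the 3' UTR through which an siRNA can lower transcripts other than its target. The siRNA sequence is not given in the sources used here, so all 16102 words of 7 bases that occur in at least 50 of 11100 genes with a searched 3' UTR were ranked by the shift of genes carrying them. The word that led under vehicle was CCGTGCT (z -5.71, 574 genes, family-wise permutation p = 0.001, the smallest that 1000 permutations give). The permutations shuffled genes, so this p covers neither correlation between genes nor the spread between samples. Under TGFb, in libraries not shared with the vehicle comparison, the word ranked 77 (z -3.08). The next words under vehicle were almost as strong, CAGCCCC (z -5.63) and GCCCCAG (z -5.14), but ranked 9353 and 1586 under TGFb, and over all words z did not correlate between treatments (r -0.007), so a low z under vehicle is not specific to a seed. The shift over all carriers was small, with a median log2 change of -0.007 against 0.009 for the other genes. Of the 41 searched genes called lower under vehicle 13 carry it, including Arl2bp, Pea15a, Ampd2, Med10 and Icmt, which were also lower under TGFb, but not Nr1d1, against 1 of 33 called higher and 5.17% of all (Fisher's exact p = 7.63e-08, two-sided, on genes picked from the same data). Other carriers did not fall under TGFb, as a seed effect would require: Slc25a10 was called higher there (log2 0.20, limma adjusted p = 0.00881), and Anapc11 (0.07), Atp6v0c (0.01) and Nol12 (-0.02) were not called. Without the genes called lower the word ranked 3 under vehicle (z -4.99) and 172 under TGFb (z -2.58). The word also occurs in all 4 protein-coding Arntl transcripts, at base 926 of the longest, in its coding part, but so do 16.8% of the searched words in at least 1 of them. The word that led under TGFb, ATTTATT (z -5.58, family-wise permutation p = 0.001), ranked 7131 under vehicle. The rank of 77 is consistent with a seed effect on genes such as Arl2bp and Pea15a, which may then not depend on Bmal1; the siRNA's sequence or a second siRNA would test this.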
